A study of Mus musculus with 6 samples.

How the data were processed

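Small RNA sequencing profiles of 6 mouse libraries were analysed, 3 from interscapular brown adipose tissue (BAT_EPA, numbered 3, 4 and 5 in the labels) and 3 from inguinal subcutaneous adipose tissue (SAT_EPA, numbered 1, 3 and 8). Per the labels' protocols, the tissues were frozen after a fast of 4 hours, total RNA was isolated, and libraries were made with an Illumina small RNA protocol. Per the series' design text, reads were mapped to mouse build mm10, counts of each unique read were scaled to total usable reads, 40 counts were added, and about 13.8 M reads were mapped per sample. The aligner, the miRNA annotation and the trimming steps are not given in the sources used here.

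The deposited table holds log2 values that the authors computed, for 1251 miRNA arms in 6 columns. The values themselves show a floor at 3.32 on the log2 scale (10 on the linear scale), a maximum of 18.67, and 910 miRNAs at the floor in all 6 libraries. The 40 added counts do not show as an offset. Of the 100 highest ranks, 64.0% held a single value in all 6 libraries within 1e-06, and the largest range at one rank was 0.139, which is how quantile normalization with averaged ties would leave the table; no source used here names that step. Since the libraries were given nearly equal distributions, their totals carry no depth, every difference is relative to the rest of the library, and the share of the library in the top ranks is largely fixed. The read depth of each library is unknown, so no counting interval or detection limit is given, and a miRNA at the floor is described as listed at the floor, without a fold. Differences against low values near the floor understate the change. The number of miRNAs above the floor was 235 to 273 per library.

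The tissues were compared with limma 3.58.1 in R 4.3.3 on the log2 values as deposited, with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. A miRNA was tested if its mean, after the floor was subtracted on the linear scale, was at least 24.05 linear units, set as a fixed small share of the mean library total, which left 269; a filter 10 times as strict was an alternative. Differences are brown minus subcutaneous, with the standard error (SE) of the fit. Of 24 lists of miRNAs by function, genomic cluster, family or cell type, 20 had 3 or more tested arms and were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, with adjustment over lists. With 6 libraries the setting with an estimated correlation had little power. The smallest camera p of any list there was 0.048 before adjustment, so a loss in that setting says little about a single list. The share of the library in the 10 most abundant miRNAs was compared with an exact two-sided permutation test. The labels do not say whether libraries of the 2 tissues came from the same mice or whether the number 3 marks one mouse in both, and p-values measure the spread between these samples as left by the normalization. Where all libraries of a tissue hold a single value, that tissue adds no spread. This holds at the floor (30 calls) and for some miRNAs above it, among them miR-378a-3p, let-7c-5p, let-7a-5p, miR-486-5p and miR-5105. The SE and p of such miRNAs can be too small.

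The miRNAs named were set by a rule: the 10 largest positive and 10 largest negative differences among calls whose groups did not overlap, the 5 most abundant, and up to 3 tested members of each list with the largest differences. This gave 77 miRNAs; further ones are said to have been chosen after their values were seen. Lists, tests and most alternatives were fixed before the data were examined. The alternatives were other pseudocounts, filters, scalings and variance models, leaving out each library, leaving out both libraries numbered 3, the more abundant arm of each list member, and an estimated correlation. Added after seeing the data were collapsing identical rows, leaving out the 2 libraries highest in miR-133a-3p, removing each library's trend with GC content, and adding arms with a locus number to their lists, also with an estimated correlation. The library share without 1 library was first computed with the 10 miRNAs chosen again; that is now an added alternative, and the planned one keeps the 10 chosen over all 6 libraries.

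Hairpin positions and host genes came from GENCODE M21 on GRCm38, the assembly also called mm10, and were matched by hairpin name. The GC content of an arm was taken from the side of the hairpin that holds it, a stand-in for the mature sequence, for 237 of the tested miRNAs (88.1%). Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for permutation tests and plots. The fit was tested on simulated data: 20 sets of values for the 269 miRNAs with the means and spreads of the libraries, in each of which 60 miRNAs were changed. Recovery was 37.75% for a log2 change of 1, 70.5% for 2 and 83.75% for 3. On average 4.92% of calls were unchanged miRNAs, and sets without any change gave 0 calls on average. Noise was drawn independently for each miRNA, with 1 spread for both tissues. Tissues that hold a single value after normalization were therefore not reproduced, and fewer miRNAs were changed than the 186 called in the data. These rates do not vouch for the p-values of the deposited values.

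Pairs of miRNAs with identical values in all 6 libraries cannot be told apart, among them miR-486-5p with miR-3107-5p and miR-199a-3p with miR-199b-3p. Libraries from mice fed the high fat diet without EPA and from visceral fat were not analysed here, so no effect of EPA was tested.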

Results

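MiRNA abundance was measured in brown and subcutaneous adipose tissue of C57BL/6J mice, an inbred laboratory strain. The mice were 5 to 6 weeks old when feeding began, and for 11 weeks received a diet with 45% of its energy from fat, 20% from protein and 35% from carbohydrate. In the libraries used here it was supplemented with 6.75% eicosapentaenoic acid (EPA), a long-chain omega-3 fatty acid. There were 3 libraries of interscapular brown fat, the main heat-producing depot, and 3 of inguinal subcutaneous fat, a white depot. The series asks how EPA alters adipose miRNAs; with the EPA-fed groups alone, the comparison is between the tissues. The deposited values are normalized log2 abundances, and the read depth of each library is unknown from them.

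The most abundant miRNA differed by tissue. In all 3 brown libraries it was miR-378a-3p, which is encoded in an intron of Ppargc1b, a coactivator of mitochondrial gene expression (GRCm38 chromosome 18, 61397835 to 61397900, minus strand). It was 10.3-fold higher in brown fat (log2 difference 3.37 ± 0.11 SE, n = 3 per tissue, limma adjusted p = 5e-06). In all 3 subcutaneous libraries it was let-7c-5p, a member of a family of miRNAs linked to cell differentiation. Let-7c-5p was 6.75-fold higher there (n = 3 per tissue, limma adjusted p = 5e-06). Both miRNAs held the maximum of the table in all 3 libraries of the tissue they led. That tissue added no spread, so the SE and p of both can be too small. The maximum was the same in every library, so both folds depend on the normalization. Among the 5 most abundant, miR-181a-5p was 1.96-fold higher in subcutaneous fat and miR-125a-5p was 1.88-fold higher in brown fat (both limma adjusted p = 0.0018); the miR-181a-5p difference was -0.28 with an adjusted p of 0.190 when the GC trend of each library was removed. For miR-22-3p the difference was -0.64 ± 0.26 SE, adjusted p = 0.063; without SAT_EPA 1 it was -0.82 with an adjusted p of 0.032, and with the GC trend removed -0.96 (0.0062).

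Of the 269 tested miRNAs, 90 were higher and 96 lower in brown fat at an adjusted p of 0.05, together 69.1%. Differences of over 2 on the log2 scale were found in 58 of the former and 56 of the latter. The 3 values of one tissue lay wholly above those of the other for 199 miRNAs (74%), where chance gives 10%. Libraries correlated at 0.936 to 0.973 within brown fat, at 0.915 to 0.963 within subcutaneous fat and at 0.612 to 0.752 between the tissues (Pearson's r across tested miRNAs, which are not independent replicates). The first principal component held 80.5% of the variance and separated the tissues. The median difference of all tested miRNAs was -0.45, and -0.09 after median-of-ratios scaling, which gave 101 higher and 82 lower.

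The miRNAs with the largest excess in brown fat included both arms of miR-129, the miR-193b and miR-365 pair, and miR-455-3p, an activator of brown adipocyte differentiation encoded in an intron of Col27a1 (chromosome 4, 63256851 to 63256932). MiR-129-2-3p stood at 11.30 ± 0.41 (SD, n = 3) in brown and 3.83 ± 0.88 in subcutaneous fat, where 2 of the 3 libraries were at the floor. MiR-455-3p was 56.9-fold higher in brown fat (5.83 ± 0.77 SE, adjusted p = 0.00092), and 33.5-fold without SAT_EPA 1 and 99.6-fold without SAT_EPA 3. MiR-129-5p (10.27 ± 0.45 SD in brown fat), miR-365-1-5p (9.10 ± 0.51), miR-6366 (8.99 ± 0.49) and miR-6240 (8.79 ± 0.83) were listed at the floor in all 3 subcutaneous libraries. MiR-2137 was 52.2-fold higher and miR-5105 47.9-fold (27.9-fold with 40 added to the deposited values). MiR-6243 stood at 11.28 ± 0.84 in brown and 5.95 ± 2.28 in subcutaneous fat, with SAT_EPA 1 at the floor; the log2 difference was 4.02 without that library and 6.07 without SAT_EPA 3.

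Lowest in brown fat relative to subcutaneous fat were miR-196a-5p, both arms of miR-335, miR-340-5p, miR-196b-5p, miR-298-5p and miR-224-5p. All of these were listed at the floor in the 3 brown libraries. In subcutaneous fat, miR-196a-5p stood at 10.81 ± 0.11 (SD, n = 3), miR-335-3p at 10.78 ± 0.40, miR-335-5p at 8.21 ± 0.49, miR-340-5p at 9.21 ± 0.70, miR-196b-5p at 8.52 ± 0.42, miR-298-5p at 8.24 ± 0.67 and miR-224-5p at 7.85 ± 0.64. MiR-335 lies in an intron of Mest (chromosome 6, 30741299 to 30741396), an imprinted gene whose expression tracks fat mass expansion. MiR-223-3p, a myeloid miRNA, was lower in brown fat, as were miR-708-5p and miR-199b-5p, with at least 1 brown library of each at the floor. In subcutaneous fat these stood at 9.36 ± 0.53, 9.69 ± 0.37 and 8.51 ± 0.53; the log2 difference of miR-708-5p (-5.12 ± 0.59 SE) was -4.49 without BAT_EPA 4.

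**Figure D1:**
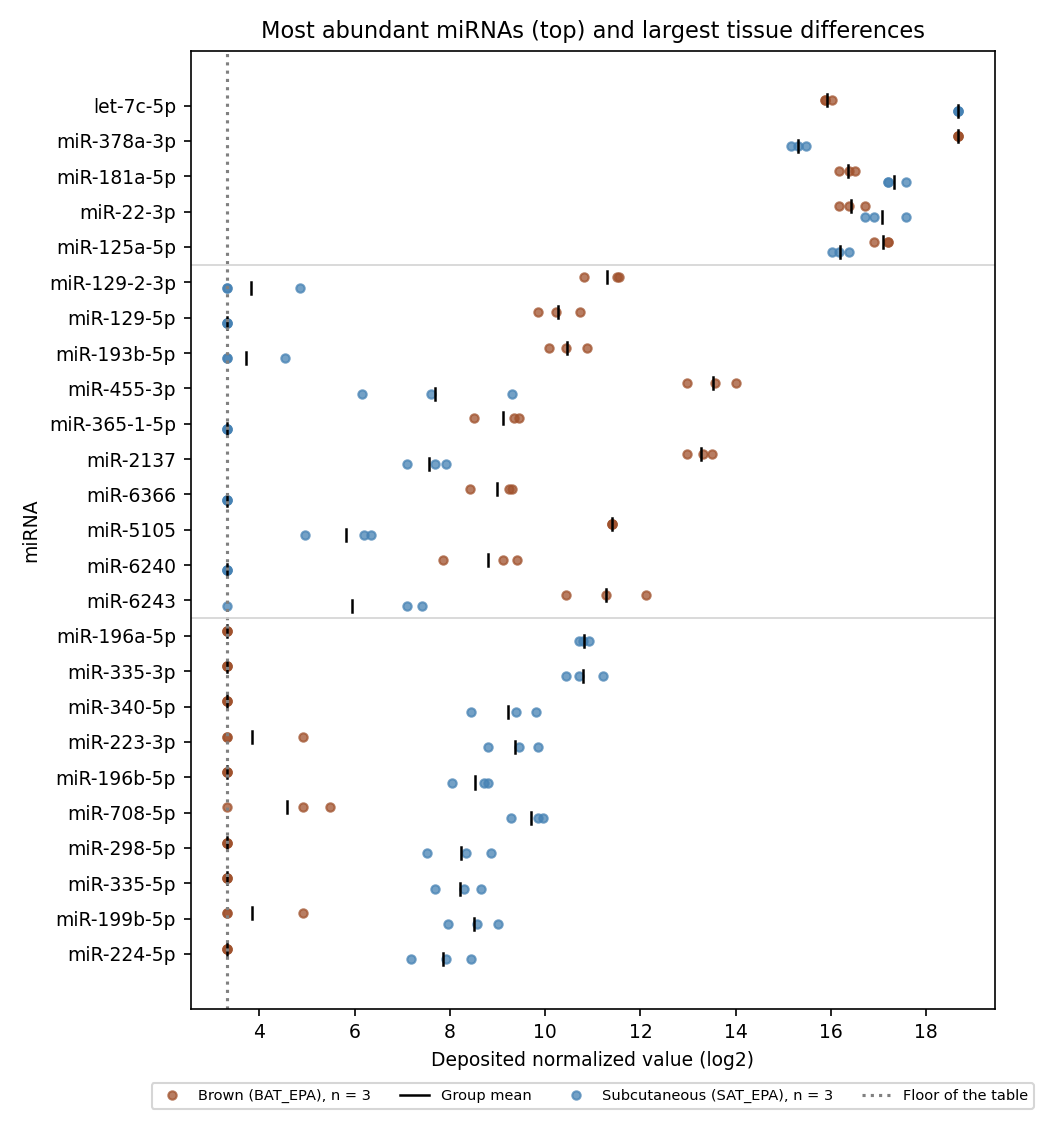
Deposited normalized values (log2) of the 5 most abundant miRNAs, the 10 with the largest excess in brown fat and the 10 with the largest excess in subcutaneous fat. Each point is a library, black bars are means of 3 libraries, and the dotted line is the floor of the table, where 7 of the lower 10 miRNAs sit in all brown libraries.

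MiRNAs reported to promote brown fat were mostly higher in brown fat: of 15 tested arms, 11 were higher and 3 lower, and the counts adjusted over the list alone were also 11 and 3. Lists were matched by name and so left out arms with a locus number (such as miR-365-1-5p). With 5 of these added after the data were seen, 15 of 20 were higher and 3 lower (camera adjusted p = 0.008, but adjusted p = 0.512 with an estimated correlation). Examples were miR-193b-3p at 15.4-fold (3.95 ± 0.23 SE) and miR-365-3p at 2.33-fold (1.22 ± 0.20 SE), besides miR-378a-3p and miR-455-3p. The 3 lower arms were miR-193a-3p, miR-26a-5p and miR-30b-5p, which were placed on the list as promoters of brown or beige adipocyte differentiation. The list as a whole was higher (camera adjusted p = 0.041), but adjusted p = 0.518 with an estimated correlation. The adjusted p was also past 0.05 without BAT_EPA 3 (0.051), BAT_EPA 5 (0.0567) or SAT_EPA 3 (0.0852), and 0.0648 after median-of-ratios scaling. The 11 higher arms include both arms of miR-378a and of miR-193b. With only the more abundant arm of each member the camera adjusted p was 0.145, and 0.0828 with the stricter filter. Without both libraries numbered 3 it was 0.0819, and without the 2 libraries highest in miR-133a-3p 0.0677. The miR-193b-365 cluster, on chromosome 16 at 13449523 to 13449601 for miR-193b and 13453840 to 13453926 for miR-365-1, had all 3 listed arms higher (also 3 adjusted over the list alone; camera adjusted p = 0.075, and adjusted p = 0.492 with an estimated correlation). MiR-365-3p is also encoded on chromosome 11. With miR-365-1-5p of the same locus and miR-365-2-5p of chromosome 11 added, again after the data were seen, all 5 were higher (camera adjusted p = 0.019, but adjusted p = 0.504 with an estimated correlation).

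The 5 tested miRNAs encoded in Hox clusters, which carry positional identity along the body axis, were lower in brown fat in 4 cases and higher in 0 (also 4 and 0 adjusted over the list alone). MiR-10b-5p, in introns of Hoxd3 and Hoxd4 (chromosome 2, 74726070 to 74726137), was 7.71-fold higher in subcutaneous fat, and miR-196b-5p lies in an exon of Hoxa9 (chromosome 6, 52230081 to 52230165). The list was lower with a camera adjusted p of 0.041, but adjusted p = 0.492 with an estimated correlation. That estimate was negative (-0.15). The rise of the unadjusted camera p from 0.0062 to 0.048 therefore does not come from correlation between members. At the preset correlation the list's adjusted p was past 0.05 without BAT_EPA 3 (0.0541), BAT_EPA 4 (0.0626), BAT_EPA 5 (0.0674) or SAT_EPA 3 (0.0684), and without a filter (0.0843). With the stricter filter the camera adjusted p was 0.129, and 0.0525 with only the more abundant arm of each member. Without both libraries numbered 3 it was 0.0780, and without the 2 libraries highest in miR-133a-3p 0.0677.

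Of 10 tested arms of miRNAs abundant in fibroblasts and smooth muscle cells of the stroma, 8 were lower in brown fat and 0 higher, or 9 lower adjusted over the list alone. MiR-199a-5p was 20.9-fold higher in subcutaneous fat (12.7-fold with 40 added to the deposited values), and miR-199a-3p, which has the same values as miR-199b-3p, was 11.9-fold higher there. MiR-199a-3p and miR-199b-3p were both counted in the 10 and in the 8, and both entered camera, though they cannot be told apart. The call of miR-145a-3p (-3.21 ± 0.82 SE, adjusted p = 0.012; -3.97 without BAT_EPA 4), with 2 brown libraries at the floor, was lost without BAT_EPA 3 (0.0525), BAT_EPA 5 (0.0522) or both libraries numbered 3 (0.0745), and with the GC trend removed (0.0669). The list was lower in brown fat with a camera adjusted p of 0.032, and adjusted p = 0.492 with an estimated correlation. With arms of lower abundance left out its adjusted p was 0.0627, and 0.0828 with the stricter filter.

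**Figure D2:**
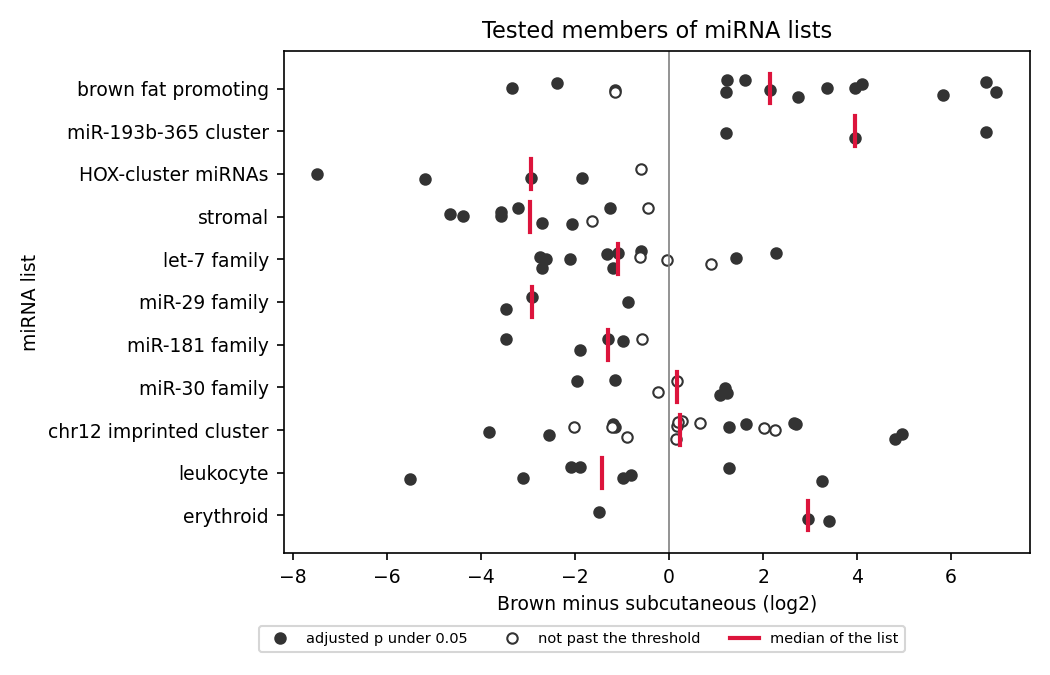
Brown minus subcutaneous difference (log2) of each tested member of 11 miRNA lists, filled where the adjusted p is under 0.05, with a red bar at each list's median (2.15 for brown fat promoting, -2.95 for Hox clusters, -2.96 for stromal). Members with a tissue at the floor are drawn at the difference from the floor, which understates them.

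Within miRNA families, arms differed in size and often in direction. Of 13 tested let-7 arms, 8 were lower and 2 higher in brown fat (the same adjusted over the list alone), with let-7a-5p 6.51-fold and let-7e-5p 6.19-fold higher in subcutaneous fat; camera gave an adjusted p of 0.330. All 3 miR-29 arms, repressors of collagen genes, were lower in brown fat (3 adjusted over the list alone; camera adjusted p = 0.246). For miR-29a-3p (1.82-fold higher in subcutaneous fat) the direction turned when the GC trend of each library was removed, to 0.92, and the call was lost with median-of-ratios scaling (adjusted p = 0.0673). The miR-29b-3p call was also lost with the GC trend removed (adjusted p = 0.127). Of 5 listed miR-181 arms, 4 were lower and 0 higher (camera adjusted p = 0.246), but with 2 arms that carry a locus number 5 were lower and 1 higher of 7 (camera adjusted p = 0.263). Beside miR-181a-5p, the miR-181b-5p call was lost with the GC trend removed (adjusted p = 0.0742) or without both libraries numbered 3 (0.0583). That of miR-181d-5p was lost without both numbered 3 (0.09996) or without the 2 libraries highest in miR-133a-3p (0.0786). The miR-30 family split, with 3 arms higher and 2 lower of 7 listed (camera adjusted p = 0.688), or 4 and 2 of 9 with locus-numbered arms (camera adjusted p = 0.524): miR-30c-5p was 2.36-fold higher in brown fat and miR-30a-5p 3.87-fold higher in subcutaneous fat. Arms of the clusters of miR-23, miR-27 and miR-24 were lower in 4 and higher in 1 of 7 listed cases (camera adjusted p = 0.330), or 5 and 1 of 8 with miR-24-2-5p (camera adjusted p = 0.246); the miR-23b-3p call was lost with the GC trend removed (adjusted p = 0.119). Of 8 listed arms of the miR-17 cluster and its paralogs, which promote cell proliferation, 2 were higher and 2 lower (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.779), and 2 and 2 of 9 with a locus-numbered arm (camera adjusted p = 0.887). Of these, miR-25-5p was not past the threshold (limma adjusted p = 0.074) and passed only under alternatives, such as without SAT_EPA 3 (0.0064). Both tested arms of the miR-34 and miR-449 family, which includes transcriptional targets of p53, were lower in brown fat; the miR-34a-5p call (1.89-fold higher in subcutaneous fat) was lost without BAT_EPA 3, BAT_EPA 5, SAT_EPA 3 or SAT_EPA 8 (adjusted p 0.0539 to 0.0623), and its difference was 0.26 with the GC trend removed. The 1 higher arm of the miR-23, miR-27 and miR-24 clusters, miR-27a-5p, lost its call without BAT_EPA 3 (adjusted p = 0.0535) or BAT_EPA 5 (0.0566), and miR-93-3p of the miR-17 paralogs without BAT_EPA 3 (0.135), BAT_EPA 4 (0.0661), BAT_EPA 5 (0.110) or SAT_EPA 3 (0.0508). Of the miR-183-96-182 cluster, miR-182-5p was 4.43-fold higher in brown fat with an adjusted p of 0.047 (8.4-fold without SAT_EPA 1), which lay between 0.0746 and 0.155 without any one of BAT_EPA 3, 4 or 5 or SAT_EPA 3 or 8, and miR-183-5p had a difference of -0.39 ± 0.81 SE (0 of 2 adjusted over the list alone). In each of these families, the counts adjusted over the list alone were those over all miRNAs except where stated.

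The imprinted miRNA cluster on chromosome 12, between Dlk1 and Dio3, had 20 tested arms, of which 6 were higher and 4 lower in brown fat (6 and 4 adjusted over the list alone; camera adjusted p = 0.412). MiR-668-3p stood at 8.69 ± 0.40 (SD, n = 3) and miR-433-3p at 8.88 ± 0.29 in brown fat, each with 2 of the 3 subcutaneous libraries at the floor, and miR-434-5p was listed at the floor in brown fat and stood at 7.16 ± 0.43 (SD, n = 3) in subcutaneous fat.

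MiRNAs reported to promote or restrain adipogenesis, the formation of fat cells, were not separated from other miRNAs by camera. Of 13 promoting arms, 5 were lower and 3 higher in brown fat (camera adjusted p = 0.412), with miR-21a-5p 9.8-fold and miR-26b-5p 9.53-fold higher in subcutaneous fat. Of 10 restraining arms, 6 were lower and 1 higher, miR-27a-5p (camera adjusted p = 0.110; the call of miR-27a-5p was lost without BAT_EPA 3, adjusted p = 0.0535, or BAT_EPA 5, 0.0566), with miR-138-5p listed at the floor in brown fat and at 7.66 ± 0.50 (SD, n = 3) in subcutaneous fat. Of 17 arms reported to restrain brown fat, 6 were lower and 3 higher, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.412); with 2 locus-numbered arms 8 were lower and 3 higher of 19 (camera adjusted p = 0.263). The counts of the first 2 of these lists were the same adjusted over the list alone.

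Some miRNAs of other cell types also differed, though no list of them passed camera apart from the stromal list above. Of 8 listed leukocyte arms, 6 were lower and 2 higher in brown fat (camera adjusted p = 0.412), or 7 and 3 of 10 with locus-numbered arms (camera adjusted p = 0.447). Beside miR-223-3p, the lymphocyte miRNA miR-150-5p was 2.41-fold higher in brown fat. The call of miR-146a-5p (log2 difference -3.10, adjusted p = 0.024), with BAT_EPA 4 at the floor, was lost without BAT_EPA 3 (0.0623), BAT_EPA 4 (-2.27, 0.0596), SAT_EPA 1 (0.0535) or SAT_EPA 8 (-2.45, 0.0864); without SAT_EPA 3 the difference was -3.74. Of 3 lymphocyte arms 2 were higher and 1 lower (camera adjusted p = 0.464), the last being miR-342-3p, whose call was lost without BAT_EPA 3 (adjusted p = 0.0578) or BAT_EPA 5 (0.0604), and with median-of-ratios scaling (0.186) or the GC trend removed (0.132). Both arms of the endothelial miR-126 were lower in brown fat, miR-126-3p by 4.1-fold; the miR-126-5p call was lost with median-of-ratios scaling (adjusted p = 0.101), without both libraries numbered 3 (0.0786) and without the 2 libraries highest in miR-133a-3p (0.0622). Among red cell miRNAs, miR-486-5p, in an intron of Ank1, was 7.71-fold higher in brown fat, while miR-451a, abundant in erythrocytes, was 2.8-fold higher in subcutaneous fat; 2 of 3 arms were higher and 1 lower (camera adjusted p = 0.557). The other higher arm, miR-486-3p, was past the threshold with an adjusted p of 0.034, which lay between 0.072 and 0.114 without BAT_EPA 3, 4 or 5 or SAT_EPA 8. The liver miRNA miR-122-5p stood at 8.19 ± 2.30 (SD, n = 3) in brown fat, with BAT_EPA 4 at 5.60, and was listed at the floor in subcutaneous fat (1 of 1 higher, with an adjusted p of 0.0814 without both libraries numbered 3). Of 4 neuronal arms 1 was lower (camera adjusted p = 0.412). MiR-212-3p and miR-132-3p were not past the threshold (limma adjusted p = 0.127 and 0.213). Under alternatives, miR-212-3p passed without BAT_EPA 5 (adjusted p = 0.0184). With the GC trend removed, miR-212-3p (-2.88, adjusted p = 0.0265) and miR-132-3p (-1.005, 0.0282) passed. Of 4 myomiR arms, which are muscle miRNAs, and of 4 epithelial arms, 0 passed the threshold (camera adjusted p = 0.847 and 0.688). Counts adjusted over the list alone were the same for all of these.

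Muscle and epithelial miRNAs differed between libraries of one tissue. MiR-133a-3p stood at 17.20 in BAT_EPA 4 and 16.90 in SAT_EPA 3, against 10.32 to 13.32 in the other 4 libraries. Without these 2 libraries 85 miRNAs were higher and 91 lower in brown fat. MiR-205-5p, an epithelial miRNA, stood at 15.02 in SAT_EPA 1, 7.35 in SAT_EPA 3 and 5.74 in SAT_EPA 8, and was listed at the floor in brown fat (adjusted p = 0.054, and 0.011 without SAT_EPA 1 or 0.0324 without SAT_EPA 8).

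**Figure D3:**
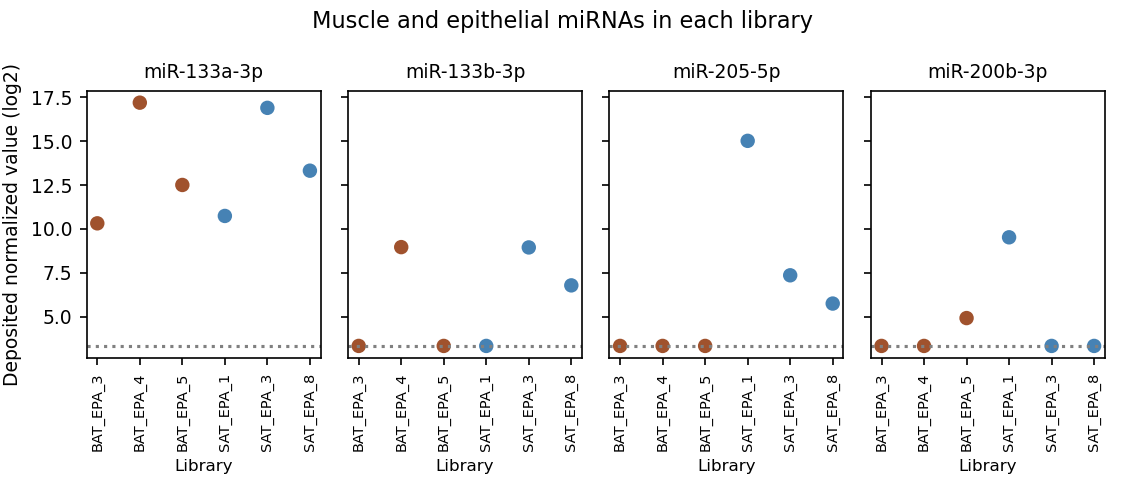
Deposited normalized values (log2) of 2 muscle and 2 epithelial miRNAs in each library, brown in brown and subcutaneous in blue, with the floor dotted. MiR-133a-3p is highest in BAT_EPA 4 and SAT_EPA 3, and miR-205-5p and miR-200b-3p in SAT_EPA 1.

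The 10 most abundant miRNAs held 57.67% ± 1.84 (SD, n = 3) of the brown libraries and 55.09% ± 1.21 (SD, n = 3) of the subcutaneous ones, a difference of 2.58 points that the exact two-sided permutation test did not separate from 0 (p = 0.3, with 0.1 the smallest possible). It turned to -2.83 points with the 5 most abundant miRNAs and to -2.58 with 20. With the same 10 miRNAs it was 1.75 to 3.57 when 1 library was left out; when the 10 were also chosen again it was 8.58 without SAT_EPA 1 and 10.45 without SAT_EPA 8.

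The tissue difference rose with the GC content of the arm. Over 237 miRNAs, Spearman's rho was 0.322 and Pearson's r 0.322 (permutation p = 0.0001 for each, the smallest that 10000 permutations can give; adjusted p = 0.0002 over 4 relations; miRNAs are not independent replicates), and r was 0.302 without the 2 miRNAs of most extreme GC content. The median difference was -1.32 over the 60 miRNAs of lowest GC content (up to 45.7%) and 0.66 over the 59 of highest (from 58.2%). After the GC trend of each library was removed, 116 of 160 calls with a GC value kept their direction and their side of the threshold. It moved some folds given above by over 1.5 times with the call kept: among those higher in subcutaneous fat, let-7a-5p to 2.89-fold, miR-10b-5p to 3.01-fold and miR-21a-5p to 4.43-fold; among those higher in brown fat, miR-486-5p to 4.08-fold, miR-30c-5p to 5.8-fold, miR-365-3p to 6.12-fold and miR-182-5p to 8.33-fold.

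**Figure D4:**
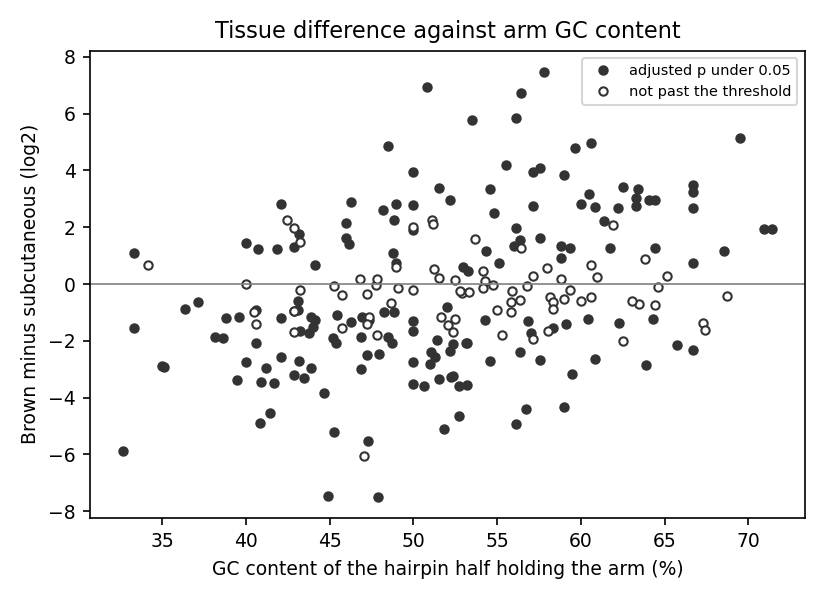
Brown minus subcutaneous difference (log2) against the GC content (%) of the side of the hairpin that holds the arm, for 237 tested miRNAs, filled where the adjusted p is under 0.05. The cloud rises from left to right, with a Spearman's rho of 0.322.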

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

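The alternatives chosen after the data were seen were collapsing identical rows, leaving out the 2 libraries highest in miR-133a-3p, removing the GC trend of each library, adding arms with a locus number to their lists (also with an estimated correlation), and choosing the 10 most abundant miRNAs again when a library was left out. No paired analysis was possible because the groups share only the number 3. Rows with one mature name could not be collapsed, since no name occurred more than once, and a count model was not run, since the values are not counts. The run without a filter used the 341 miRNAs above the floor in any library. Over all settings, the number of miRNAs higher in brown fat was 58 with the stricter filter, where fewer miRNAs were tested (157), and 72 to 101 elsewhere, and the number lower was 68 to 98. Leaving out 1 library gave 75 to 91 higher and 86 to 96 lower. Removing the GC trend left 72 higher and 68 lower of 237. Subtracting the floor and adding 10 gives back the deposited values, so that alternative repeats the main fit. Equal totals and quantile normalization kept 186 and 184 of 186 calls, in libraries that already had nearly equal distributions. Of the 66 named miRNAs past the threshold, 50 kept direction and call under every alternative that tested them. The other 16 lost the call in at least 1: miR-122-5p, miR-126-5p, miR-145a-3p, miR-146a-5p, miR-181a-5p, miR-181b-5p, miR-181d-5p, miR-182-5p, miR-23b-3p, miR-27a-5p, miR-29a-3p, miR-29b-3p, miR-342-3p, miR-34a-5p, miR-486-3p and miR-93-3p. Most of the 66 were named by the size of their difference in these data, so their stability is partly built in. Over all calls, 159 (without BAT_EPA 3) to 176 (without SAT_EPA 3) stayed when 1 library was left out, of 182 to 185 tested. Without both libraries numbered 3, 151 of 185 stayed, and 165 of 186 without the 2 libraries highest in miR-133a-3p. Depth per library is unknown, so what depth limits could not be set.

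The number of lists past the threshold, 3, was 4 with locus-numbered arms added, and became 0 with the stricter filter, with only the more abundant arm or with an estimated correlation, also with locus-numbered arms, and 1 without both libraries numbered 3 or without the 2 libraries highest in miR-133a-3p. It ranged from 1 to 3 when 1 library was left out: 1 without BAT_EPA 3, BAT_EPA 5 or SAT_EPA 3. With an estimated correlation the smallest camera p before adjustment was 0.048 (Hox clusters), so the 0 there says little about a single list. The difference in library share changed to -2.83 points with the 5 most abundant miRNAs and to -2.58 with 20, and ranged from 1.75 to 3.57 when 1 library was left out with the 10 miRNAs kept. With the 10 chosen again as well it ranged from 1.75 to 10.45 (8.58 without SAT_EPA 1, 10.45 without SAT_EPA 8).

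Of the named miRNAs, 3 not past the threshold and 2 past it changed sign. The difference of miR-133a-3p (-0.31) became 0.11 with median-of-ratios scaling, 1.199 without BAT_EPA 3, 0.10 without BAT_EPA 5, 1.31 without SAT_EPA 3 (-2.24 to 1.31 over single libraries left out) and 2.82 without both libraries numbered 3. That of miR-133b-3p (-1.15) became 0.15 without SAT_EPA 3 (-3.02 to 0.15) and 1.09 without both numbered 3. For miR-183-5p (-0.39) it became 0.011 with median-of-ratios scaling, 0.55 without SAT_EPA 1 (-0.93 to 0.55) and 0.54 with the GC trend removed. With the GC trend removed miR-29a-3p (-0.87) became 0.92 and miR-34a-5p (-0.92) became 0.26. The cause was not tested.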

Other observations

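The tests chosen only after a result was seen were the GC test of differences over 2 on the log2 scale, the share of late-numbered entries in exons, those entries as a group, the 2 settings that remove the GC trend or the libraries rich in miR-133a-3p, the weight given to miR-1a-3p, and the neighbour and arm counts with the miRNAs named beside them.

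Some miRNAs encoded side by side differed between the tissues in opposite ways. In the cluster that holds miR-99b, let-7e and miR-125a, miR-99b-5p was higher in brown fat (log2 difference 1.18 ± 0.17 SE; -0.235 with the GC trend removed) and let-7e-5p lower (-2.63 ± 0.17). On the X chromosome, miR-351-5p was higher (0.74 ± 0.15) and miR-322-5p lower (-2.39 ± 0.21). MiR-497-5p (-2.33 ± 0.16) and miR-195a-5p (-3.56 ± 0.31), a pair with a shared seed, were both lower. Over 65 pairs of hairpins within 10000 bases on one strand, the median size of the difference between neighbours was 1.79, against 2.63 after shuffling (permutation p = 0.03), and 63.1% had the same sign against 49.2%; pairs of one cluster share members, so they are not independent. Of 21 hairpins with both arms past the threshold, 6 had arms that went in opposite directions: let-7d, miR-1843b, miR-193a, miR-27a, miR-93 and miR-99b. Of these 6, only miR-1843b kept both calls in all 20 alternatives, which include the setting that repeats the main fit. With the GC trend removed, let-7d-5p turned to 0.575, the direction of its 3p arm, miR-99b-5p turned sign, and miR-93-3p lost its call (adjusted p = 0.0795); let-7d-5p also lost its call with median-of-ratios scaling (0.219). The miR-93-3p call was also lost without BAT_EPA 3 (0.135), BAT_EPA 4 (0.0661), BAT_EPA 5 (0.110) or SAT_EPA 3 (0.0508), that of miR-27a-5p without BAT_EPA 3 (0.0535) or BAT_EPA 5 (0.0566), and that of miR-193a-5p without both libraries numbered 3 (0.0909) or the 2 libraries highest in miR-133a-3p (0.0659).

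Of the 10 ways to split the 6 libraries into 3 and 3, too few for a share under 0.05, 1 gave as many miRNAs higher in one group as the tissue split (90; highest other 0), and 1 as many lower (96; highest other 0).

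Tissue difference and GC content: the trend across miRNAs may come from the libraries rather than the tissues, since both arms of a hairpin come from one transcript and the arm difference still followed the GC difference over 53 hairpins (rho 0.37, permutation p = 0.0051, 95% bootstrap 0.082 to 0.60). Removing each library's GC trend kept 116 of 160 calls (72.5%) in the same direction, and the median size of all 160 went from 2.437 to 2.049, that of the 44 lost from 1.53 (SE 0.29) to 0.39 (SE 0.31). Of the 44, 4 turned sign and passed in the opposite direction, miR-186-5p, let-7d-5p, miR-29a-3p and miR-15b-5p. Of differences over 2 on the log2 scale 80 of 94 stayed (85.1%), but a set picked by size tends to stay past a threshold, so this excludes nothing. GC bias and a tissue difference cannot be told apart, since the correction would also remove tissue differences that follow GC content and tissue choice of arm was untested.

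Other cell types: miR-133a-3p was high in BAT_EPA 4 and SAT_EPA 3, and a candidate source is skeletal muscle carried along with the fat. The other tested myomiR arms followed it with a median r of 0.919 once tissue means were removed, but these 3 arms were at the floor in 3 to 5 of the 6 libraries, and miR-1a-3p, among the most abundant muscle miRNAs, was listed at the floor in all 6, so muscle remains open as the source; miR-142-3p was at the floor too, beside miR-142-5p at up to 9.01. The tissue difference did not rest on those 2 libraries, since 100% of calls kept their direction and at least 0.5 of their size without them. The calls were picked with BAT_EPA 4 and SAT_EPA 3 included, and miR-133a-3p stood at 10.32 to 13.32 in the libraries kept. A part played by muscle in those libraries is therefore not excluded. For miR-486-5p, more red blood cells in brown fat were argued against by miR-451a, whose difference was -1.49 with an upper 95% limit of -0.69. That argument rests on miR-451a alone, since miR-144-3p, another red cell miRNA, was listed at the floor in all 6 libraries. Sources of miR-486-5p other than red cells were not tested. Within each tissue its other arm, miR-486-3p, was highest in BAT_EPA 4 (10.29) and SAT_EPA 3 (7.60), the libraries highest in miR-133a-3p. MiR-486-5p itself stood at 17.68 in every brown library and was highest among subcutaneous ones in SAT_EPA 8 (15.09). Whether the tissues differ in other ways was not tested.

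Late-numbered entries: of 23 tested miRNAs with a number of 2000 or above, 18 were higher in brown fat and 0 lower, against 72 and 96 of 246 others (Fisher's exact p = 5.4e-06). The group was formed after values were seen and miRNAs are not independent replicates, so that p only describes the counts. Such entries are often less well characterised, and some could be fragments of longer RNAs; other miRNAs inside exons differed from the rest by -0.048 (permutation p = 0.941), a test that holds none of these entries and so excludes nothing, and 33.3% of the 18 with a single locus lie in exons (95% exact interval 13.3% to 59.0%) against 25.1% of others, which leaves it open. Against other miRNAs of like hairpin GC content, the 18 entries with a hairpin stood 3.636 higher (95% bootstrap 1.968 to 5.474). For those 18 this argues against hairpin GC content as the whole account of the excess. They are only 78.3% of the entries, under a limit of 80% set for checks of GC content over a whole group. GC bias therefore stays open for the group. Of the 18 entries that were higher, miR-3107-5p has the values of miR-486-5p, and a difference between the tissues stays open for the rest, untested.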
